A study of Mus musculus with 3 samples.

How the data were processed

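RNA sequencing values were available for 3 mouse melanoma cell lines, YUMM2.1, YUMM1.1 and YUMM1.7, with 1 library of total RNA per line. The RNA was extracted with a Qiagen AllPrep kit and the libraries were made with a standard Illumina protocol, per the submitters' notes. Per the submitters' processing notes, reads were aligned with TopHat2 2.0.9 and expression was estimated with Cufflinks and Cuffnorm, whose versions are not given in the sources used here. The deposited values are FPKM (fragments scaled by transcript length and library size) per gene symbol, made by the authors. The genome build, the annotation, any filter and the scaling between libraries are not given in the sources used here. The 25791 symbols held 0 repeats, so symbols needed no merging.

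Read counts were not used here, so depth was inferred from the values. In genes with a single transcript of at least 3000 nt, low FPKM values multiplied by transcript length clustered at multiples of a step, which is the value of 1 fragment. Of the low values, 82.4%, 82.3% and 82.4% lay within 0.2 of a whole multiple in YUMM2.1, YUMM1.1 and YUMM1.7. The steps of 0.01145, 0.01455 and 0.02185 FPKM times kb imply 87.3, 68.7 and 45.8 M scaled fragments. On simulated counts the largest error of this depth was 5.03%. At 1 FPKM a 2 kb transcript would hold about 175, 137 and 91.5 fragments, which covers counting error only and says nothing of differences between cultures. The FPKM sums were 693156, 1041960 and 1827830, and the 50 highest symbols held 34.1%, 39.8% and 50.3% of them.

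The comparisons, the gene lists, the rule for named genes and the alternatives were chosen before the data were examined, apart from the alternatives named as added. Values were taken as deposited and read as log2(FPKM + 1), for the 11741 symbols with an FPKM of at least 1 in at least 1 line. A gene was counted as higher or lower at a difference of 2 or more (4-fold on that scale), without a p-value. Pearson's r and Spearman's rho were computed across genes. The 29 fixed gene lists covered tumor drivers, melanocyte, mesenchymal and neural crest states, signaling targets, antigen processing, interferon response, immune ligands and cytokines, growth and stress programs, matrix, markers of other cell types, sex-linked genes and gene families. For lists with 5 or more expressed members, the median difference was set against 10000 random lists of the same size, drawn from 20 bins of mean expression. A list was said to stand apart below percentile 2.5 or above 97.5, and its members were counted at a difference of 1 (2-fold). Lists with fewer members were given as values, and no symbol of the mitochondrially encoded genes was in the table.

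Named genes were the 12 highest and the 12 lowest in YUMM2.1 against both other lines (by the smaller difference) and in YUMM1.7 against YUMM1.1, leaving out predicted genes, small RNAs and pseudogenes. Up to 4 members with the largest difference were added from each list, and a fixed set of driver, pigmentation and immune genes was named whatever its values. Some genes that this rule names are not reported here. Alternatives were other pseudocounts (0.1 and 5), no filter and a filter at 5 FPKM, rescaling to a common sum, to a common upper quartile or by the median ratio, leaving out predicted and small RNA symbols, and random lists without matching. Random lists matched on transcript length and the removal of genes listed at 0 were added after the data were seen.

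Transcript length, GC content and chromosome came from a mouse reference annotation that need not be the one the authors used, so no coordinates are given; 93.4% of the expressed symbols had a length and 95.6% a chromosome. The count rule was tried on counts simulated from the YUMM1.1 values at the implied depths of YUMM1.1 and YUMM1.7, with fragment counting error only. It found 2 of 49 genes changed 4-fold, 39 of 50 changed 8-fold, 47 of 50 changed 16-fold and 44 of 50 changed 32-fold. It called 0 of 10310 unchanged genes, which says nothing of calls that come from differences between cultures or library preparations. Of 2000 lists of 16 genes drawn at random, with their own differences between YUMM1.7 and YUMM1.1, 4.85% stood apart. Of such lists with every member raised by 1, 99.8% stood apart above. The first rate checks the calculation only, since those lists came from the same pool as the random lists. It says nothing of lists whose genes vary together. A shift of -0.5 planted on a chromosome was found as -0.43, with the other chromosomes between -0.05 and 0.07. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.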

Results

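Bulk RNA sequencing was available for 3 mouse melanoma cell lines, YUMM2.1, YUMM1.1 and YUMM1.7, from a series on the response to PD-1 blockade in mice bearing transplanted melanoma. YUMM (Yale University Mouse Melanoma) lines were derived from melanomas of genetically engineered mice and can be grown in immunocompetent mice of the same strain. PD-1 is an inhibitory receptor of T cells. The labels name no treatment and no tumor response for any library. Each line was sequenced as 1 library of total RNA, without replicates. The differences describe these libraries, carry no p-value and cannot be set against a spread between cultures. Expression was given as FPKM for 25791 gene symbols, of which 11741 had an FPKM of at least 1 in at least 1 line. Total counts were not given, but the spacing of the lowest FPKM values implied about 87.3 M scaled fragments for YUMM2.1, 68.7 M for YUMM1.1 and 45.8 M for YUMM1.7. Abundant genes such as Rpl41 were listed at 0 in YUMM1.7, so a value listed at 0 is given as such and is not read as absence of expression. At these depths 3 fragments on a 2 kb transcript correspond to 0.0172, 0.0218 and 0.0328 FPKM, counting error only.

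YUMM2.1 and YUMM1.1 had the most similar profiles, and YUMM1.7 differed from each of them. Across expressed genes, which are not independent replicates, Pearson's r of log2(FPKM + 1) was 0.934 between YUMM2.1 and YUMM1.1, 0.865 between YUMM1.7 and YUMM1.1 and 0.848 between YUMM2.1 and YUMM1.7 (Spearman's rho 0.909, 0.823 and 0.799). By a fixed rule of a 4-fold difference on the FPKM + 1 scale, 173 genes were higher and 130 lower in YUMM2.1 than in YUMM1.1. Against YUMM1.7, YUMM2.1 had 367 higher and 650 lower genes, and YUMM1.7 against YUMM1.1 had 464 higher and 359 lower genes. YUMM2.1 lay beyond both other lines for 71 higher and 49 lower genes, YUMM1.1 for 68 and 67, and YUMM1.7 for 321 and 191. The balance of higher and lower genes depended on the pseudocount and on the scaling of the libraries. With a pseudocount of 5, YUMM2.1 against YUMM1.1 had 44 higher and 57 lower genes, and with a pseudocount of 0.1, YUMM1.1 against both others had 129 and 253. After each line was rescaled to a common sum, the counts were 313 higher and 85 lower for YUMM2.1 against YUMM1.1, 1517 and 188 for YUMM2.1 against YUMM1.7, and 255 and 601 for YUMM1.7 against YUMM1.1. For YUMM2.1 against both others that scaling gave 174 and 24 genes and a common upper quartile gave 93 and 39. For YUMM1.7 against both others the sum scaling gave 143 and 445. The median difference of all genes was -0.05, -0.02 and 0.02 as deposited and 0.43, 1.08 and -0.59 after the sum scaling, in the same order of comparisons.

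**Figure D1:**
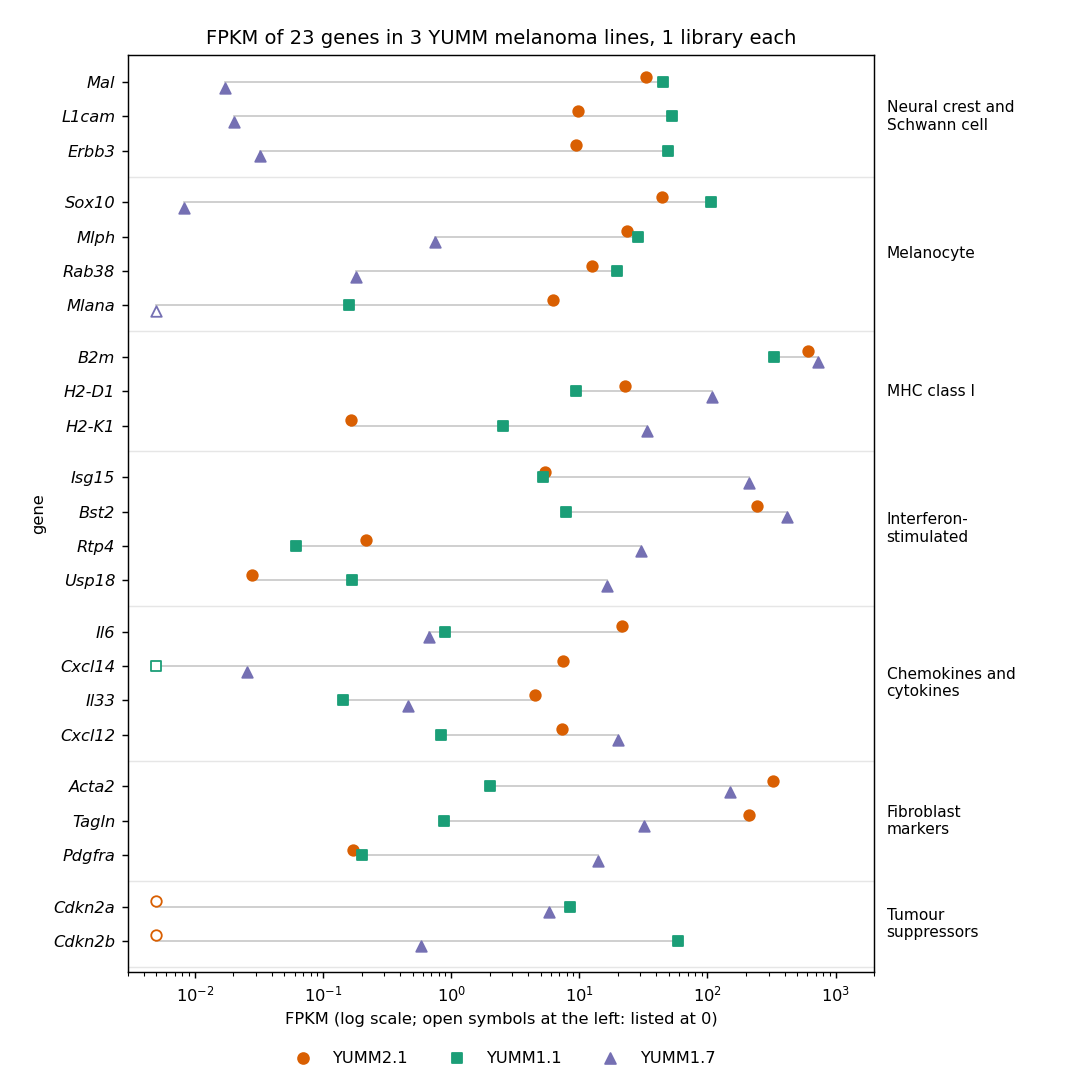
FPKM of 23 genes (vertical axis, grouped by gene list) in YUMM2.1, YUMM1.1 and YUMM1.7, 1 library each, on a log axis; open symbols at the left edge are genes listed at 0. Sox10 stands at 44.3 in YUMM2.1, 107 in YUMM1.1 and 0.00821 in YUMM1.7, and Isg15 at 5.38, 5.24 and 212.

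The first comparison asked what sets YUMM2.1 apart from both other lines. Aldh1a1, which encodes a retinaldehyde dehydrogenase, was the gene most in excess in YUMM2.1, at 464 FPKM against 1.45 in YUMM1.1 (321-fold) and 0.157 in YUMM1.7. The matrix genes Fbln2 (32.7 FPKM), Col11a1 (20.4 FPKM) and Thbs2 (17.4 FPKM) were all below 0.3 FPKM in the other lines. Il6, an inflammatory cytokine, stood at 21.4 FPKM against 0.896 in YUMM1.1 and 0.672 in YUMM1.7. Raet1d, which encodes a ligand of the natural killer cell receptor NKG2D, stood at 33.0 against 2.36 and 1.23. In the opposite direction, Mtap, which encodes an enzyme of methionine salvage and lies beside Cdkn2a, was listed at 0 in YUMM2.1 and stood at 59.4 FPKM in YUMM1.1 and 83.7 in YUMM1.7.

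The other genes among the 12 highest were Fxyd1, a regulator of the sodium pump (117 FPKM in YUMM2.1, 0.194 in YUMM1.1, listed at 0 in YUMM1.7), Acox2 (22.8 FPKM, 0.0807 and listed at 0), Rab17 (23.3 FPKM), Gstk1 (15 FPKM), Snurf (12.1 FPKM) and the protease inhibitor Serpine2 (124 FPKM against 11.9 and 1.11). Their smaller difference from the other lines ranged from 3.28 for Serpine2 to 7.57 for Aldh1a1 on the log2(FPKM + 1) scale. Among the 12 lowest after Mtap were Cdk2ap2 (0.537 FPKM in YUMM2.1, 47.8 in YUMM1.1, 104 in YUMM1.7), Rhod (0.23, 32.8 and 75.0), the quinone reductase gene Nqo1 (2.23, 61.6 and 397), the tubulin gene Tuba1c (3.18, 58.3 and 187) and Grb10 (0.0801, 12.8 and 17.3). Nudt14, Hpcal1 and Pcyt2 were each below 1 FPKM in YUMM2.1 and above 13 FPKM in both other lines. Ppap2b was listed at 0 in YUMM2.1. Klhl9, another neighbor of Cdkn2a, stood at 0.00272 FPKM against 19.3 and 9.84, and Ly6a, which encodes the surface antigen Sca-1, at 0.295 against 115 and 9.77.

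Against YUMM1.1, chemokine and cytokine genes were higher in YUMM2.1, with 12 of 26 expressed members at least 2-fold higher and 1 at least 2-fold lower. The median difference of the list was 0.83, above all 10000 random lists of the same size and expression. After Il6, the members furthest apart were Cxcl14 (7.41 FPKM, listed at 0 in YUMM1.1), the alarmin Il33 (4.52 against 0.142) and Cxcl12 (7.31 against 0.839), a chemokine that attracts leukocytes through CXCR4. In the same comparison the leukocyte markers Lyz2 (25.9 against 4.96 FPKM), Cd68 (4.27 against 0.362) and Cd53 (3.01 against 0.0215) were also higher in YUMM2.1. Genes of MHC class I antigen processing had a median of 0.25 (percentile 99.3), with 4 of 16 members higher and 2 lower. Tap2 (2.46 against 0.146 FPKM), Tap1 (1.62 against 0.102) and H2-D1 (22.9 against 9.38) were higher, and H2-K1 was lower (0.166 against 2.52). With members kept only at an FPKM of 5 or more the median of that list was 0.01, at percentile 93.7. MAPK output genes, which report signaling downstream of Braf, had a median of 0.26 (percentile 98.9) with 2 of 17 higher and 1 lower, among them Egr1 (difference 1.64), Dusp5 (1.43) and Fosl1 (-1.03). Against random lists that were not matched, the MAPK list lay at percentile 97.3 and the MHC class I list at 96.3, both within the random range. Against YUMM1.7 these lists did not stand apart. The cytokine median was -0.27 there (percentile 7.41, 11 of 26 higher and 8 lower). The MHC class I median was -0.63 (percentile 17.0, 2 of 16 higher and 7 lower). The MAPK median was 0.33 (percentile 94.5, 5 of 17 higher and 4 lower).

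Hox genes had higher values in YUMM2.1 than in YUMM1.1, where 8 of the 13 expressed members were listed at 0. Of the 13, 10 were at least 2-fold higher and 0 lower (median 1.14, above all random lists). With genes listed at 0 left out, too few members remained to evaluate the list. The members furthest apart were Hoxb7 (18.7 FPKM, listed at 0 in YUMM1.1), Hoxd8 (4.39 against 0.0114), Hoxd13 (2.98, listed at 0) and Hoxb4 (2.33 against 0.0059). Against YUMM1.7 the Hox list did not stand apart (median -0.03, percentile 18.1, 4 of 13 higher and 2 lower). Neural crest and Schwann cell genes were lower in YUMM2.1 than in YUMM1.1 (median -0.73, percentile 0.18, 2 of 14 higher and 5 lower). Among the lower genes were the myelin-associated gene Cnp (5.52 against 55.9 FPKM), L1cam (9.79 against 52.5) and Erbb3 (9.50 against 49.7). Targets of Wnt and beta-catenin signaling had a median of -0.58 (percentile 1.69), with 0 of 9 members higher and 2 lower: Sox4 (8.61 against 31.0 FPKM) and Nkd2 (18.1 against 38.0). Ccnd1 stood at 462 against 865 FPKM and Lef1 at 1.27 against 2.51. The call for that list ended with a pseudocount of 5 (percentile 6.71), without a filter (9.40) and with a filter at 5 FPKM (5.72). Against YUMM1.7 the Wnt list did not stand apart (median -0.10, percentile 35.3, 3 of 9 higher and 1 lower). Ribosomal protein genes, short and abundant, were lower in YUMM2.1 than in YUMM1.1 (median -0.77, percentile 0.055, 0 of 77 higher and 21 lower), with Rpl29, Rps6, Rpl37 and Rps23 at differences of -1.54 to -1.49. Short transcripts in general read lower in that comparison. Of 5 equal classes of transcript length, the shortest had a median of -0.35 and the longest of 0.19.

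Against YUMM1.7, the neural crest and Schwann cell genes were the group most in excess in YUMM2.1, with 10 of 14 members at least 2-fold higher, 1 lower and a median difference of 3.33, above all random lists. Among the higher genes were Mal (33.1 against 0.0171 FPKM), the adhesion gene Ncam1 (75.1 against 3.49) and Pmp22 (154 against 12.2). Melanocyte differentiation genes were also higher (median 1.02, percentile 99.6, 5 of 9 higher and 0 lower). Sox10, a transcription factor of the neural crest and melanocyte lineage, stood at 44.3 against 0.00821 FPKM. The melanosome genes Mlph and Rab38 stood at 23.5 against 0.751 and at 12.7 against 0.179. The call for that list ended under a pseudocount of 5 (percentile 92.8) and under the sum scaling (percentile 94.3). Integrin, claudin and cadherin genes were higher (median 1.19, 13 of 23 higher and 4 lower). Itga4 stood at 34.3 against 0.152 FPKM, Cdh19 at 27.1 against 0.0145 and Itga1 at 12.3 against 0.314, while Cdh13 was lower at 0.481 against 19.5. Without a filter the median of that list was 0 (percentile 45.5). Targets of p53 were higher as well (median 0.54, percentile 99.5, 5 of 21 higher and 0 lower). Among them were the death genes Pmaip1 (5.34 against 0.597 FPKM) and Fas (5.87 against 0.997) and the p53 antagonist Mdm2 (28 against 11.3).

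Interferon-stimulated genes were lower in YUMM2.1 than in YUMM1.7 (median -1.25, below all random lists, 2 of 30 higher and 18 lower). They were led by Ly6e (0.0474 against 38.7 FPKM), Isg15 (5.38 against 212), Rtp4 (0.215 against 30.5) and Usp18 (0.0278 against 16.4). Fibroblast marker genes had a median of -1.67 (percentile 0.05, 2 of 8 higher and 5 lower), with Pdgfra at 0.170 against 13.9 FPKM and Cd34 at 0.328 against 11.7, but the contractile gene Tagln was higher at 213 against 32. Genes of a dedifferentiated mesenchymal state had a median of -0.70 (percentile 2.18, 5 of 21 higher and 9 lower), which turned to 0.64 under the sum scaling, where the median of all genes was 1.08. The call ended there (percentile 5.53), with a pseudocount of 0.1 (3.41), with a filter at 5 FPKM (26.7) and with genes listed at 0 left out (6.40). Within this list Tgfbi (0.305 against 29.1 FPKM) and Snai1 (0.0472 against 14.6) were lower and Ngfr (31.5 against 0.0643) and Thbs1 (56.5 against 5.58) higher in YUMM2.1. Ribosomal protein genes had a median of -1.83, with 63 of 77 lower and 4 higher. Those 4 were listed at 0 in YUMM1.7, among them Rpl41, Rps12 and Rpl13a. Genes of short transcripts were lower in YUMM2.1 than in YUMM1.7 in general. Among 5 equal classes of transcript length, the shortest had a median of -0.82 and the longest of 0.40.

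**Figure D2:**
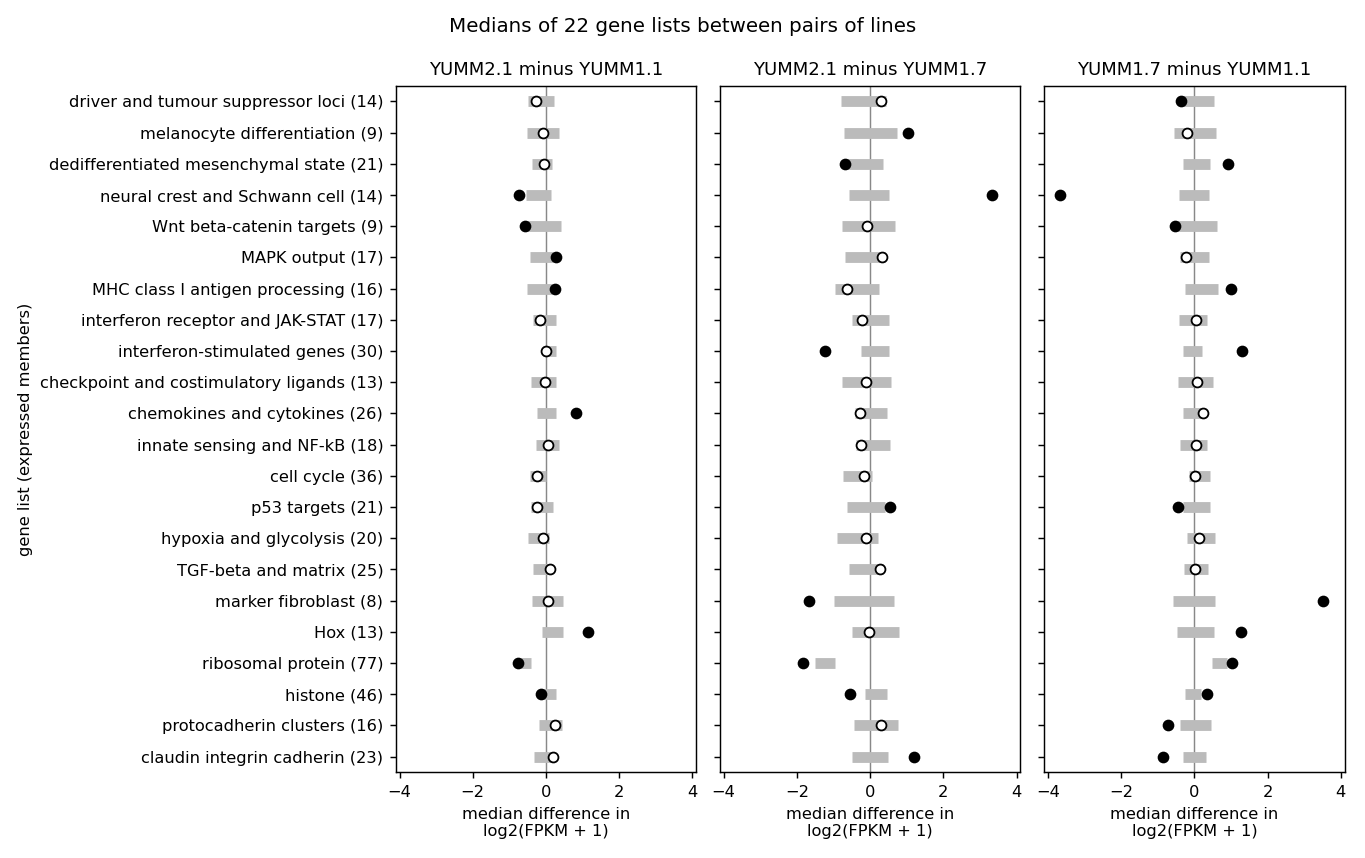
Median difference of log2(FPKM + 1) over the expressed members of 22 gene lists (points) in the 3 comparisons of lines, with the range that holds the middle 95% of 10000 random lists of the same size and expression (grey bars); filled points stand apart from it. The neural crest and Schwann cell list lies at -3.66 and the fibroblast marker list at 3.51 in YUMM1.7 minus YUMM1.1.

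The second comparison set YUMM1.7 against YUMM1.1, the lines that share the first number in their names. Neural crest and Schwann cell genes were much lower in YUMM1.7, with 11 of 14 expressed members at least 2-fold lower, 2 higher and a median difference of -3.66, below all random lists. The adhesion gene L1cam stood at 0.0203 FPKM in YUMM1.7 and 52.5 in YUMM1.1, the neuregulin receptor gene Erbb3 at 0.0324 and 49.7 and Mal at 0.0171 and 45.2. Fibroblast marker genes went the other way, with 7 of 8 at least 2-fold higher and 0 lower (median 3.51, above all random lists). The smooth muscle actin gene Acta2 stood at 149.6 against 2.0 FPKM, Tagln at 32 against 0.886, and the PDGF receptor genes Pdgfrb at 13 against 0.0107 and Pdgfra at 13.9 against 0.202. Acta2 and Tagln were also abundant in YUMM2.1, at 326 and 213 FPKM.

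The genes most in excess in YUMM1.7 were Crabp1, which encodes a retinoic acid binding protein (2206 FPKM against 0.644 in YUMM1.1 and 0.0807 in YUMM2.1), and Mgp, an inhibitor of matrix calcification (2557, 1.47 and 1.64). They were followed by Cyba, a subunit of the NADPH oxidase (741 against 0.0499 FPKM), Lgals7 (763 against 0.21), Arhgdib (833 against 0.775), the proteoglycan gene Bgn (261 against 0.0191), Klra4 (195 against 0.0622) and Igfbp6 (192 against 0.0512). Next came the lymphatic and stromal marker Pdpn (152, listed at 0 in YUMM1.1), Glipr1 (229 against 0.538), the BMP antagonist Grem1 (135 against 0.0097) and the collagen gene Col1a2 (127 against 0.0367). Cyba and Bgn were high in YUMM2.1 too, at 110.5 and 104 FPKM. Among the 12 genes lowest in YUMM1.7 were Ecel1 (0.116 against 644 FPKM), the nerve growth factor receptor gene Ngfr (0.0643 against 421), S100a16 (1.67 against 642), the matrix gene Postn (0.407 against 162) and Sox10 (0.00821 against 107). Also among them were Rpl41, Rps12, Rpl13a, Rn18s and Moxd1, which were listed at 0 in YUMM1.7 and stood at 36747 FPKM for Rpl41 and 111 for Moxd1 in YUMM1.1. These zeros are not read as low expression.

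Interferon-stimulated genes were higher in YUMM1.7 than in YUMM1.1, with 20 of 30 members at least 2-fold higher, 3 lower and a median of 1.29, above all random lists. Bst2, which encodes the virus-tethering protein tetherin, stood at 416 against 7.81 FPKM, the ubiquitin-like modifier gene Isg15 at 212 against 5.24, Rtp4 at 30.5 against 0.061 and Oas1a at 14.2 against 0.00826. Bst2 was also high in YUMM2.1 (246 FPKM), whereas Isg15 was not (5.38 FPKM). The MHC class I list had a median of 0.99 (percentile 99.9, 8 of 16 higher and 0 lower). H2-D1 stood at 109 against 9.38 FPKM, H2-K1 at 33.6 against 2.52, H2-T23 at 18.4 against 3.03 and the immunoproteasome gene Psmb8 at 3.66 against 0.109. Short transcripts read higher in YUMM1.7, with a median of 0.48 in the shortest of the 5 length classes. Against random lists matched on transcript length as well, an alternative chosen after the data were seen, the interferon-stimulated list lay above all random lists and the MHC class I list at percentile 99.9. Under the sum scaling the MHC class I median was 0.24 where that of all genes was -0.59.

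The mesenchymal list was higher in YUMM1.7 than in YUMM1.1 (median 0.92, above all random lists, 10 of 21 higher and 4 lower). Tgfbi stood at 29.1 against 0.118 FPKM, the transcription factor gene Snai1 at 14.6 against 0.121 and the fibronectin gene Fn1 at 154 against 22.3, while Ngfr was lower. Hox genes had higher values (median 1.27, percentile 99.98, 8 of 13 higher and 0 lower), with Hoxb7 at 10.2 FPKM and Hoxb2 at 4.76, both listed at 0 in YUMM1.1, Hoxd8 at 4.49 and Hoxb4 at 3.22. This rests in part on the same 8 members listed at 0 in YUMM1.1, without which too few remained, and without a filter the median was 0 (percentile 50). Targets of p53 were lower (median -0.44, percentile 0.495, 0 of 21 higher and 4 lower). The 4 were Plk2 (3.83 against 20 FPKM), the cell cycle inhibitor gene Cdkn1a (36.6 against 125), Mdm2 (11.3 against 28.8) and Ccng1 (70.1 against 145). With a filter at 5 FPKM the list lay at percentile 3.45, within the random range. Integrin, claudin and cadherin genes were lower (median -0.85, below all random lists, 5 of 23 higher and 10 lower). Cdh19 stood at 0.0145 against 23.5 FPKM, Itga4 at 0.152 against 19.6 and Itga8 at 0.717 against 14.2, and Cdh13 higher at 19.5, listed at 0 in YUMM1.1. Without a filter the median of that list was 0 (percentile 50). Clustered protocadherin genes were lower (median -0.72, percentile 0.08, 3 of 16 higher and 5 lower). They were led by Pcdhgb6 at 0.0562 against 5.08 FPKM and Pcdhgb1 at 0.0692 against 4.33. Reads of these related genes can be shared. With a filter at 5 FPKM, too few protocadherin genes remained to evaluate their list. Ribosomal protein genes had a median of 1.03 (percentile 99.95, 40 of 77 higher and 4 lower).

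Some lists stood apart only narrowly between YUMM1.7 and YUMM1.1. Wnt and beta-catenin targets had a median of -0.53 (percentile 2.31, 1 of 9 higher and 4 lower), with Nkd2 at 0.0546 against 38.0 FPKM, Ccnd1 at 169.9 against 865, Tcf7 at 1.19 against 5.90 and Apcdd1 higher at 11.9 against 3.44. Driver and tumor suppressor genes had a median of -0.37 (percentile 2.03) with 0 of 14 higher and 1 lower, Cdkn2b at 0.587 against 58.5 FPKM. Matched on transcript length as well, these lists lay at percentiles 7.98 and 4.77. Their calls also ended against random lists that were not matched (2.63 and 3.28), that for Wnt targets with a pseudocount of 5 (6.11), without a filter (72.1), under the sum scaling (10.6) and with predicted and small RNA symbols left out (2.69), and that for driver genes with a common upper quartile (2.52) and with genes listed at 0 left out (3.85). Histone genes had medians of -0.14, -0.55 and 0.34 in YUMM2.1 against YUMM1.1, YUMM2.1 against YUMM1.7 and YUMM1.7 against YUMM1.1, each with the opposite sign under the sum scaling, where the medians of all genes were 0.43, 1.08 and -0.59. Relative to random lists under that scaling they kept their side (percentiles 4.53, 0 and 99.5), the first within the random range. As deposited, they lay within the random range once length was matched (percentiles 29.7, 13 and 76.3). The histone genes furthest apart between YUMM2.1 and each other line were Hist3h2ba (44.6, 4.41 and 0.389 FPKM in YUMM2.1, YUMM1.1 and YUMM1.7) and Hist1h4i (12, 55.5 and 60.7).

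Genes that define the genetic background of melanoma models and the targets of checkpoint therapy were read in all 3 lines. Braf stood at 2.19, 1.14 and 1.09 FPKM in YUMM2.1, YUMM1.1 and YUMM1.7 and Ctnnb1, which encodes beta-catenin, at 91.8, 99.9 and 58.1. Cdkn2a was listed at 0 in YUMM2.1 and stood at 8.41 FPKM in YUMM1.1 and 5.84 in YUMM1.7. A value per gene cannot show which exons were read, so it tells nothing of an engineered allele. Among pigmentation genes, Tyr stood at 0.127, 0.261 and 0.279 FPKM, Si, the older symbol of Pmel, at 0.187, 0.318 and 0.0961 and Dct at 0.0318, 0.00677 and listed at 0. Mitf reached 1.23, 0.188 and 0.617 FPKM and Mlana 6.18 and 0.159, listed at 0 in YUMM1.7, while Axl, a receptor of dedifferentiated melanoma, stood at 125, 176 and 154. The Wnt target Axin2 was below 0.5 FPKM in each line.

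Ligands of T cell checkpoint and costimulatory receptors were read next. Cd274, which encodes PD-L1, stood at 0.604 FPKM in YUMM2.1, 0.11 in YUMM1.1 and 0.21 in YUMM1.7. Pdcd1lg2 stood at 0.0102 and 0.0128 in YUMM2.1 and YUMM1.7 and was listed at 0 in YUMM1.1. Cd80 stood at 0.422, 0.437 and 2.29, and Cd86 was listed at 0 in each. The list of checkpoint and costimulatory ligands did not stand apart in any comparison (percentiles 48.9, 38.0 and 65.1), but did in YUMM2.1 against YUMM1.1 with a filter at 5 FPKM (median 0.43, percentile 98.9). Lgals3 (152, 26.9 and 487 FPKM), Lgals9 (4.65, 32.8 and 23.2), the ectonucleotidase gene Nt5e (7.47, 0.648 and 0.0244) and Cd200 (10.2, 21.6 and 0.048) differed between lines. The interferon receptor and JAK-STAT list did not stand apart either (percentiles 21.8, 15.6 and 71.9), with Ifngr1 at 18.8, 21.2 and 9.06 FPKM and Irf1 at 13.6, 17.2 and 13.2. B2m was abundant in every line (608, 330.3 and 723 FPKM) and the class I transactivator gene Nlrc5 was not (0.0178, 0.00828 and 0.606).

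Markers of other cell types were read for cells that a culture could hold. Ptprc, the pan-leukocyte marker CD45, stood at 0.00217 FPKM in YUMM2.1 and was listed at 0 in the other lines. Of the leukocyte list, 4 of 26 genes reached 1 FPKM: Lyz2 (25.9, 4.96 and 0.048), Cd68 (4.27, 0.362 and 0.687), Cd53 (3.01, 0.0215 and 0.658) and S100a8 (17.0, 3.93 and 12.7). Of the keratinocyte and epithelial markers Krt10 and Sfn reached 1 FPKM, of the endothelial and erythroid markers Flt1 and Egfl7, of the MHC class II genes H2-DMa and H2-DMb1, and of the germline and cancer-testis genes 0 of 22. The remaining lists of 5 or more expressed genes did not stand apart in any comparison. Their percentiles in the order used above were 55.2, 7.53 and 70.4 for innate sensing and NF-kB, 37.7, 82.7 and 22.8 for the cell cycle, 73.6, 75.5 and 45.1 for hypoxia and glycolysis, and 94.5, 93.2 and 52.3 for TGF-beta and matrix genes. The matrix list stood apart in YUMM2.1 against YUMM1.7 under the sum scaling (percentile 99.3), with a filter at 5 FPKM (percentile 99.97) and with genes listed at 0 left out (percentile 98.3). Over all 22 lists and 3 comparisons, 30 of 66 medians stood apart, where 3.3 would for lists of randomly drawn genes. The 66 medians are not independent, since the comparisons share libraries and some lists share genes, so the excess is not a test.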

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

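No paired analysis was possible because each line has 1 library. The random lists matched on transcript length and the removal of genes listed at 0 were chosen only after the data were seen, and the other alternatives before. Rescaling by the median ratio is a weak check, as it changed the values little. The median of all genes became -0.02, 0.01 and 0.02, from -0.05, -0.02 and 0.02 as deposited, in the order of comparisons used above. This rescaling left the 12 counts, the 6 correlations and 65 list medians within the bounds set for a move. The exception was integrins, claudins and cadherins in YUMM2.1 against YUMM1.1, at the upper bound as deposited, which stood apart there (0.24) and with a pseudocount of 5 (0.13), the filter at 5 FPKM (0.22), a common sum (0.77) and a common upper quartile (0.38). The alternative for repeated symbols gave no values because 0 symbols were repeated. Of the values of named genes under the alternatives 934 stayed within the bounds and 168 moved beyond them, and of the counts 74 and 34. Depth limits genes near 0.0172, 0.0218 and 0.0328 FPKM in YUMM2.1, YUMM1.1 and YUMM1.7, and the spread between cultures is unknown. Below, lists are named with their median, and a percentile is given where the list no longer stood apart or newly did. For every value below the cause was not tested, except that a larger pseudocount shrinks differences and a smaller one widens them.

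With a pseudocount of 0.1, higher and lower genes numbered 504 and 273 for YUMM2.1 against YUMM1.1, 797 and 990 for YUMM2.1 against YUMM1.7 and 830 and 672 for YUMM1.7 against YUMM1.1. Against both others they numbered 205 and 110 for YUMM2.1, 129 and 253 for YUMM1.1 and 520 and 474 for YUMM1.7. Pearson's r was 0.778 between YUMM2.1 and YUMM1.7 and 0.795 between YUMM1.7 and YUMM1.1. For YUMM2.1 against YUMM1.7 the medians were 3.26 for melanocyte genes, -0.72 for mesenchymal genes (percentile 3.41), 4.02 for neural crest and Schwann cell genes, -2.18 for interferon-stimulated genes and -3.10 for fibroblast markers. For YUMM1.7 against YUMM1.1 they were -4.44 for neural crest and Schwann cell genes, 3.28 for interferon-stimulated genes, 5.11 for fibroblast markers, 0.47 for cytokines (percentile 98.6), 3.92 for Hox genes and -1.58 for protocadherins, and for YUMM2.1 against YUMM1.1 3.71 for Hox genes.

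With a pseudocount of 5, the counts in the same order were 44 and 57, 116 and 361, and 201 and 130, and against both others 21 and 13 for YUMM2.1, 28 and 18 for YUMM1.1 and 147 and 61 for YUMM1.7. For YUMM2.1 against YUMM1.7 the medians were 0.27 for melanocyte genes (percentile 92.8), 1.58 for neural crest and Schwann cell genes, -0.50 for interferon-stimulated genes, -0.87 for fibroblast markers and 0.57 for integrins, claudins and cadherins. For YUMM1.7 against YUMM1.1 they were -2.36 for neural crest and Schwann cell genes, -0.22 for Wnt targets (percentile 6.11), 0.65 for interferon-stimulated genes, 1.76 for fibroblast markers and 0.36 for Hox genes. For YUMM2.1 against YUMM1.1 they were -0.26 for Wnt targets (percentile 6.71), 0.31 for Hox genes and -0.038 for histones (percentile 3.41).

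Without a filter, r and rho were 0.930 and 0.925 between YUMM2.1 and YUMM1.7 and 0.937 and 0.920 between YUMM1.7 and YUMM1.1. Medians over lists that then held many unexpressed members were, for YUMM2.1 against YUMM1.7, 0.045 for melanocyte genes, 0.33 for MAPK output (percentile 97.7), 0.037 for protocadherins (percentile 99.9), -0.27 for fibroblast markers and 0 for integrins, claudins and cadherins (percentile 45.5). For YUMM1.7 against YUMM1.1 they were -2.97 for neural crest and Schwann cell genes, 0.003352 for Wnt targets (reversed, percentile 72.1), 0.51 for fibroblast markers, -0.024 for protocadherins, and 0 for Hox genes and for integrins, claudins and cadherins (both at percentile 50). For YUMM2.1 against YUMM1.1 they were -0.004156 for Wnt targets (percentile 9.40), 0.035 for cytokines, 0.14 for Hox genes and -0.012 for histones (percentile 3.14). With a filter at 5 FPKM, r and rho were 0.790 and 0.727 between YUMM2.1 and YUMM1.7, and r was 0.812 between YUMM1.7 and YUMM1.1. For YUMM2.1 against YUMM1.7 the medians were then 2.84 for melanocyte genes, -0.43 for mesenchymal genes (percentile 26.7), 0.76 for matrix genes (percentile 99.97) and -2.28 for fibroblast markers. For YUMM1.7 against YUMM1.1 they were -1.47 for Wnt targets, -0.34 for p53 targets (percentile 3.45) and 0.37 for histones (percentile 94.9), and for YUMM2.1 against YUMM1.1 -0.58 for Wnt targets (percentile 5.72), 0.013 for MHC class I genes (percentile 93.7), 0.43 for checkpoint ligands (percentile 98.9) and -0.15 for histones (percentile 34). The Hox and protocadherin lists gave no value with that filter because too few members were left.

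Rescaled to a common sum, which put the median of all genes at 0.43, 1.08 and -0.59, the counts in the same order were 313 and 85, 1517 and 188, and 255 and 601, and against both others 174 and 24 for YUMM2.1 and 143 and 445 for YUMM1.7. For YUMM2.1 against YUMM1.7 the medians were 1.56 for melanocyte genes (percentile 94.3), 0.64 for mesenchymal genes (reversed in sign, percentile 5.53), -0.65 for interferon-stimulated genes, 1.56 for p53 targets, -0.43 for ribosomal proteins, 0.44 for histones (reversed in sign, but at percentile 0) and 2.09 for integrins, claudins and cadherins. For YUMM1.7 against YUMM1.1 they were -1.04 for driver genes, -0.94 for Wnt targets (percentile 10.6), 0.24 for MHC class I genes, -1.10 for p53 targets, 2.85 for fibroblast markers, 0.22 for ribosomal proteins and -0.27 for histones (reversed in sign, but at percentile 99.5). For YUMM2.1 against YUMM1.1 they were -0.18 for ribosomal proteins and 0.30 for histones (reversed in sign, percentile 4.53). Of lists that did not stand apart as deposited, medians moved for YUMM2.1 against YUMM1.7 to 1.35 for driver genes, 0.99 for Wnt targets, 1.58 for MAPK output, 0.52 for MHC class I, 0.95 for interferon receptors, 0.89 for checkpoint ligands, 0.81 for cytokines, 0.89 for innate sensing, 1.18 for the cell cycle, 1.22 for hypoxia, 1.58 for matrix genes (percentile 99.3), 1.08 for Hox genes and 0.90 for protocadherins. For YUMM1.7 against YUMM1.1 they moved to -0.92 for MAPK output, -0.67 for interferon receptors, -0.68 for checkpoint ligands, -0.081 for cytokines (percentile 99.9), -0.60 for innate sensing, -0.73 for the cell cycle and -0.67 for hypoxia. With a common upper quartile, driver genes in YUMM1.7 against YUMM1.1 had -0.39 (percentile 2.52) and histones in YUMM2.1 against YUMM1.1 0.003596 (reversed in sign, percentile 3.30).

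With predicted and small RNA symbols left out, Wnt targets in YUMM1.7 against YUMM1.1 had -0.53 (percentile 2.69). Against random lists that were not matched, driver genes (-0.37, percentile 3.28) and Wnt targets (-0.53, percentile 2.63) in YUMM1.7 against YUMM1.1 and MAPK output (0.26, percentile 97.3), MHC class I (0.25, percentile 96.3) and histone genes (-0.14, percentile 20.9) in YUMM2.1 against YUMM1.1 no longer stood apart. Matched on length, the same held for driver genes (-0.37, percentile 4.77) and Wnt targets (-0.53, percentile 7.98) in YUMM1.7 against YUMM1.1 and for histones in all 3 comparisons (-0.14, -0.55 and 0.34, percentiles 29.7, 13 and 76.3). With genes listed at 0 left out, driver genes in YUMM1.7 against YUMM1.1 had -0.31 (percentile 3.85), and mesenchymal genes (-0.56, percentile 6.40) and fibroblast markers (-2.28) differed for YUMM2.1 against YUMM1.7, where driver genes (0.63, percentile 99.6) and matrix genes (0.37, percentile 98.3) newly stood apart. The Hox list gave no value there because too few members were left.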

Other observations

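Of the tests in this part, those of failed estimates and of fibroblasts, that of segments along chromosomes and those on the genes around Cdkn2a were chosen only after the result was seen. Y-linked genes were read in all 3 lines: Ddx3y stood at 7.87, 2.44 and 3.23 FPKM in YUMM2.1, YUMM1.1 and YUMM1.7, Uty at 2.92, 0.902 and 1.26, and Kdm5d at 3.21, 1.17 and 1.58. Xist, the RNA that silences an X chromosome in female cells, was at most 0.00309 FPKM. Eif2s3y, another Y-linked gene, stood at 36.5 and 15 FPKM in YUMM2.1 and YUMM1.1 and was listed at 0 in YUMM1.7.

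Matrix genes differed gene by gene between the lines, although their list did not stand apart. Bgn stood at 104, 0.0191 and 261 FPKM in YUMM2.1, YUMM1.1 and YUMM1.7, Postn at 138, 162 and 0.407, Col1a2 at 0.651, 0.0367 and 127 and Fbln2 at 32.7, 0.0169 and 0.0349. Gsta4, a glutathione transferase gene, was listed at 0 in YUMM1.1 and stood at 6.92 and 73.1 FPKM in YUMM2.1 and YUMM1.7. Of symbols with at least 5 FPKM in both other lines, 5 were listed at 0 in YUMM2.1, 5 in YUMM1.1 and 16 in YUMM1.7.

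The neural crest and Schwann cell genes lower in YUMM1.7 were weighed first. Failed estimates listed at 0 are argued against, since 0 of the 11 lower members were listed at 0 in YUMM1.7. Fibroblasts in place of the melanoma cells were examined by 5 of their abundant transcripts. Of these, 0 of 5 were among the top 5% of YUMM1.7, a level of 284 FPKM. Col1a2 stood at 127, Col3a1 at 21.9, Col1a1 at 1.79 and Dcn at 1.40, and Lum was listed at 0. That level was set after the result was seen, so the test does not decide the question. Against YUMM1.1, Col1a2 was far higher (127 against 0.0367 FPKM) and Col3a1 lower (21.9 against 98.7). In the same comparison 7 of 8 expressed fibroblast markers were at least 2-fold higher and 0 lower. A fibroblast-like state of the YUMM1.7 cells, a smaller share of other cells and a mislabeled culture stay open as hypotheses that were not tested.

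Genes on chromosomes 4, 8, 13 and 15 were lower in YUMM2.1, with medians of -0.51, -0.51, -0.34 and -0.55 against YUMM1.1 and of -0.70, -0.78, -0.37 and -0.80 against YUMM1.7, where the other 16 chromosomes lay between -0.17 and 0.30 and between -0.07 and 0.37. Transcript length and GC content are argued against, since the weakest of the 8 medians was -0.35 after genes of like length, GC content and expression were taken off. A few genes or a local region are argued against by 32 of 32 segments below the median of all genes. Fewer copies of these chromosomes stay open as a hypothesis, since DNA was not measured. That 24 of 24 medians by chromosome, expression class and comparison lay at least 0.1 below those of the other chromosomes restates the pattern, as the chromosomes were picked for low medians and both comparisons share the YUMM2.1 library. Shifts were not confined to these chromosomes or to YUMM2.1. In YUMM2.1 against YUMM1.1, chromosomes 1 (0.30), 9 (0.26), 18 (0.25) and 14 (0.18) lay above all 10000 random gene sets. Chromosomes 16 (0.08), 3 (0.06) and 7 (0.03) did so too, and chromosome 11 (-0.17) lay below all of them. In YUMM1.7 against YUMM1.1, chromosomes 15 (0.28), 8 (0.26), 4 (0.22) and 7 (0.15) lay above all random sets. Chromosomes 12 (-0.27), 3 (-0.22), X (-0.19), 10 (-0.16) and 6 (-0.14) lay below all of them.

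Around Cdkn2a, 5 genes were at or near 0 in YUMM2.1: Mllt3 (0.0426 FPKM), Ptplad2 (listed at 0), Klhl9 (0.00272), Mtap (listed at 0) and Cdkn2a (listed at 0). They form a run of neighbors among the genes at 1 FPKM or more in both other lines, with other genes between them. Failed estimates falling by chance are argued against, since 0 of 10000 shuffled gene orders held a run as long and the longest held 3 genes. The shuffle treats each gene as failing on its own, so it cannot speak to failed estimates tied to this stretch. Loss of the whole stretch between Rps6 (495 FPKM) and Gm12669 (2.72 FPKM) stays open as a hypothesis, since DNA was not measured. Outside the run only 3 genes of the stretch, Gm12603, Cdkn2b and Dmrta1, reach 0.5 FPKM in another line, with at most 0.0421 FPKM in YUMM2.1, and these are too few to decide it.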
